A study of Mus musculus with 16 samples.

How the data were processed

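RNA was extracted with TRIzol from livers of female WT and LKO mice, and poly(A)-enriched libraries (NEBNext Ultra II) were sequenced on a NovaSeq as paired 150-base reads, with a depth of 20 M reads per the labels. The authors' notes name the mm10 build, Bowtie2 and DESeq2 without versions or roles, and neither the counting tool nor the annotation is given. The authors deposited estimated counts (expected counts) per gene symbol, of which 51.1% were whole at a tolerance of 1e-06. They were not normalised, and were rounded to whole numbers for the count models. The counts table held 15119 genes, which are exactly those above 0 in all 16 libraries of a second deposited table of 35712 genes. Genes silent in any library were thus absent from the main analysis, although these 20593 genes held little of the counts (99.93% of the counts were in the genes kept).

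The second table is named as RPKM but holds the same estimated counts. In its 8 chow columns each value stood 1 row below its gene, so that 1 gene matched the counts table on chow as deposited and 15119 after the chow columns were moved up by 1 row (relative tolerance 1e-06). A single value differed afterwards, that of Acat2 in WT HFD replicate 2, at 8555 in the counts table and 2296.5 in the second table. Acat2 is therefore not interpreted. The second table was used for the number of genes detected, for Y-linked and cilia genes, for genes outside the counts table and as an alternative. Symbols of 14532 of the 15119 genes matched GENCODE M21 (GRCm38), from which coordinates were taken.

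Total counts ran from 19142612 to 25120565 per library, and no difference in depth between groups was detected in 2-sided exact permutation tests of 4 against 4 (lowest p 0.514, smallest possible p 0.0286). More genes were detected in LKO than in WT libraries, 18660 ± 156 against 18080 ± 162 on chow and 18810 ± 148 against 18240 ± 108 on HFD (SD, n = 4 each; exact p = 0.0286, 0.143 after Benjamini-Hochberg adjustment over 20 library tests). Replicate numbers were checked for pairing. Only 5 of 24 correlations between libraries of the same number exceeded 0.1 (median -0.018), so the libraries were treated as unpaired. The labels give no batch, collection time or pairing.

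Differential expression was tested with edgeR 4.0.16 (R 4.3.3, with data.table at 1.17.8): TMM library sizes, filterByExpr with the 4 groups, quasi-likelihood fits with robust dispersion and 1 mean per group over all 16 libraries. This left 14434 genes. Tests were 2-sided and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 with no fold minimum. The contrasts were LKO against WT on chow and on HFD, HFD against chow in WT and in LKO, and their interaction. Group values are means of TMM-scaled CPM with their SD, and fold changes are fitted log2 values with their standard error. Gene lists, 37 in number, were fixed before the data were examined, as were the contrasts, the tests and the rule for named genes. The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera asks whether members changed more than other genes, and fry whether they changed at all. Where a list was called, its median, mean and camera test had the same sign. Counts within a list are given over all genes tested and adjusted over the list alone.

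The named genes were Arglu1, the 10 largest rises and 10 largest falls of each comparison among called genes with a group mean of at least 1 CPM and no overlap between libraries (2.9% of genes show none by chance), and up to 4 members with the lowest p of each list. Of these the text prefers genes whose call held in every alternative run. Other genes are named as chosen after their values were seen. Overlaps between comparisons were tested by 1-sided Fisher exact tests across genes.

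Alternatives set in advance were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors, upper-quartile scaling, no filter, a mean count of at least 50, fits of only the groups compared, a replicate block, a fold minimum of 2 and leaving out each library. Alternatives chosen after seeing the data were the second table with and without moving the chow columns, leaving out LKO chow libraries 1 and 2 or 3 and 4, a clock score as a term, and the second table's Acat2 value. The analysis was tested on simulated data: negative binomial counts drawn at the depths and dispersions of these libraries, with known changes, gave 62.7% to 77.6% of 2-fold changes called in the comparisons of 2 groups and 55.2% in the interaction, with 3 to 7 false calls. Few genes were changed and genes were drawn independently. These rates need not hold where many genes differ or vary together, as in the real libraries.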

Results

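Poly(A) RNA was measured by paired-end sequencing in 16 libraries from livers of female mice. The mice were either wild type (WT) or lacked Arglu1 in hepatocytes (LKO), and each genotype was fed chow or a high-fat diet (HFD, TD. 88137) for 12 weeks after ageing to 9 months on chow. Arglu1 encodes an arginine- and glutamate-rich protein that acts as a transcriptional coregulator and in RNA splicing. Each of the 4 groups held 4 libraries. The total estimated count per library ran from 19689661 to 23774780 in WT on chow and from 19142612 to 25120565 in LKO on chow. On HFD it ran from 20219283 to 24123730 in WT and from 19158827 to 24667513 in LKO. The labels do not say that each library is a separate animal, so all errors and p-values describe the spread between these libraries. Levels are given as CPM, the count of a gene scaled to the size of its library. The first principal component of log2 CPM, with 38.2% of the variance, separated the genotypes. The second, with 13.8%, set LKO chow libraries 3 and 4 (38.1 and 34.7) apart from LKO chow libraries 1 and 2 (-10.7 and -11.1).

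Arglu1 transcript was lower in all 8 LKO libraries than in all 8 WT libraries. On chow it averaged 41.2 ± 2.62 CPM in WT and 14.7 ± 1.56 CPM in LKO, and on HFD 42.2 ± 1.70 CPM in WT and 15.5 ± 1.53 CPM in LKO (SD, n = 4 each). The log2 fold change was -1.49 on chow (SE 0.093, adjusted p = 8.03e-09) and -1.44 on HFD (SE 0.093, adjusted p = 1.34e-08, edgeR). Single libraries spanned 39.51 to 45.1 CPM in WT and 12.76 to 16.7 CPM in LKO. Diet left no detectable mark on Arglu1, with log2 fold changes of 0.03 in WT (adjusted p = 0.911) and 0.08 in LKO (adjusted p = 0.696). The gene (ENSMUSG00000040459.11) lies on the minus strand of chromosome 8 from 8665075 to 8690521 (mm10/GRCm38). The labels do not name the exons that the knockout removes, and transcript from liver cells other than hepatocytes is counted too.

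**Figure D1:**
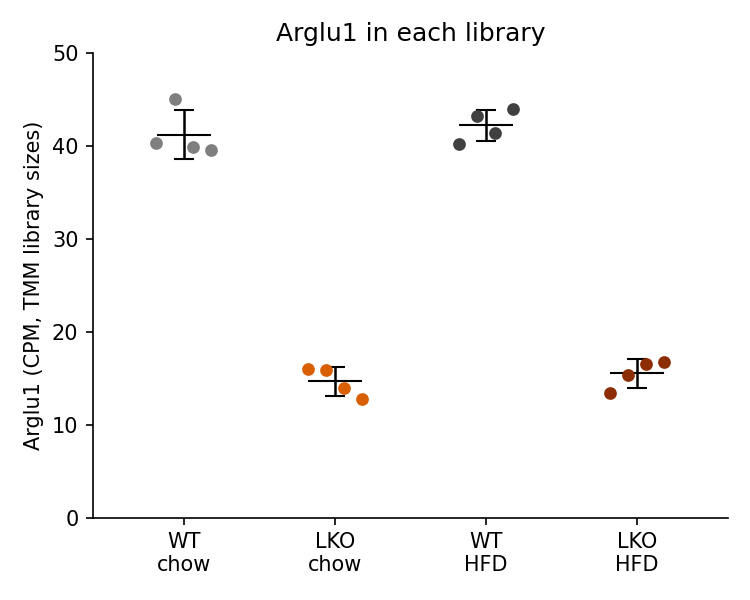
CPM of Arglu1 (vertical axis, starting at 0) in each library of the 4 groups, with the group mean and SD. The 8 WT libraries sit between 39.51 and 45.1 and the 8 LKO libraries between 12.76 and 16.7.

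The first comparison asked what loss of Arglu1 in hepatocytes did to the liver transcriptome on chow. Most targets of p53, the DNA-damage-responsive transcription factor, rose, as did most interferon-stimulated genes and most genes normally higher in male liver, while most genes normally higher in female liver fell. The largest rise in the counts table was that of Cyp4a12a, a male-biased fatty acid hydroxylase (chromosome 4, 115299046 to 115332815), from 0.0864 ± 0.0505 to 21.8 ± 9.55 CPM (SD, n = 4 each; log2 fold change 7.91, SE 0.492, adjusted p = 1.69e-08). Psrc1, a microtubule-associated protein (chromosome 3, 108383839 to 108388231), followed at 7.04 (SE 0.266, adjusted p = 1.26e-11), and the aquaglyceroporin Aqp7 (chromosome 4, 41033074 to 41048139) rose by 5.54 (SE 0.287, adjusted p = 9.08e-10). Of 14434 genes tested, 3565 (24.7%) were called, 1867 higher and 1698 lower in LKO. A change of at least 2-fold was found in 743 of the higher and 162 of the lower genes.

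On chow, 12 of 13 p53 targets rose and none fell (12 rose and 1 fell when adjusted over the list alone). Phlda3, an inhibitor of Akt signalling, rose by 4.11 on the log2 scale (SE 0.167, adjusted p = 2.9e-11), the cyclin Ccng1 by 1.51 (SE 0.12, adjusted p = 1.06e-07) and the kinase Plk2 by 1.90 (SE 0.161, adjusted p = 2.3e-07). Cdkn1a, the cell cycle inhibitor p21, was chosen after its values were seen and stood at 7.26 ± 3.22 CPM in WT and 126 ± 52.0 CPM in LKO (SD, n = 4 each; log2 fold change 4.11, adjusted p = 1.95e-06). The mean log2 CPM of the list was 5.33 ± 0.22 in LKO and 3.45 ± 0.11 in WT, and the list was called by camera (median log2 fold change 1.51, adjusted p = 3.21e-12). It was also called with an estimated correlation between genes (adjusted p = 0.0184). Interferon-stimulated genes rose in 17 of 20 members and fell in none (18 rose and 1 fell when adjusted over the list alone). Examples were Oas1a, an RNA-sensing synthetase (2.85, SE 0.186, adjusted p = 1.5e-08), the transcription factor Irf7 (1.94, SE 0.208, adjusted p = 4.99e-06) and Ifi44 (3.01, SE 0.304, adjusted p = 4.99e-06). The interferon list had a camera adjusted p = 4.52e-11, but adjusted p = 0.236 with an estimated correlation. Fry gave it adjusted p = 7.54e-05.

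Sex-biased liver genes changed in opposite directions on chow. Of 20 female-biased genes tested, 17 fell and 1 rose (18 and 1 when adjusted over the list alone), with a median log2 fold change of -2.04 and a camera adjusted p of 4.52e-11, and adjusted p = 0.0184 with an estimated correlation. Cyp3a44 fell by 3.76 (SE 0.327, adjusted p = 1.16e-06), Sult3a1, a sulfotransferase, by 4.55 (SE 0.538, adjusted p = 3.73e-05) and Cyp2b13 by 1.94 (SE 0.191, adjusted p = 1.63e-06). Of 15 male-biased genes, 11 rose and none fell (12 and none when adjusted over the list alone), with a median of 1.54, a camera adjusted p of 1.37e-09 and adjusted p = 0.00815 with an estimated correlation. Besides Cyp4a12a these included the urinary pheromone-binding protein Mup20 (6.04, SE 0.471, adjusted p = 4.95e-07) and Cyp2d9 (3.34, SE 0.237, adjusted p = 6.16e-08). Many of these genes belong to families of near-identical copies (Cyp2, Cyp3a, Cyp4a, Sult and Mup), between which reads cannot be assigned with certainty, so the size of each such change is uncertain. Among the other large falls on chow were Steap2, a metalloreductase (-2.73, SE 0.241, adjusted p = 3.57e-07), the radial spoke protein Rsph4a (-3.18, SE 0.476, adjusted p = 0.000116) and the inducible chaperone Hspa1b (-2.82, SE 0.425, adjusted p = 0.000233).

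Splicing regulators of the serine/arginine-rich class fell in 11 of 26 members and rose in 1 on chow (13 and 1 when adjusted over the list alone). Srrm1 fell by 0.62 (SE 0.11, adjusted p = 0.000549), Srsf3 by 0.43 (SE 0.096, adjusted p = 0.00356) and Srsf2 by 0.54 (SE 0.124, adjusted p = 0.00407). Camera called the list (median -0.28, adjusted p = 0.00236), with adjusted p = 0.575 with an estimated correlation and 0.0323 by fry. The camera call was lost when LKO chow libraries 1 and 2 were left out. Those 2 libraries had list means of 5.72 and 5.71, against 5.98 and 6.04 in LKO chow libraries 3 and 4. In LKO on chow, B and plasma cell genes had a median of -0.91 (3 of 13 fell and none rose, 4 and none when adjusted over the list alone; camera adjusted p = 0.00855, adjusted p = 0.575 with an estimated correlation). Markers of Kupffer cells, neutrophils and endothelial cells held no called gene on chow among 10, 5 and 17 tested. Those of macrophages and monocytes held 2 rises of 20 (1 when adjusted over the list alone), and those of T and NK cells 1 of 16 (1 when adjusted over the list alone), the pore-forming protein Prf1 (2.05, SE 0.378, adjusted p = 0.000769). Extracellular matrix and stellate cell genes held 1 rise of 23 (none when adjusted over the list alone). Bile duct cell genes held 2 of 12 (2 when adjusted over the list alone), among them the adhesion protein Cdh1 (2.72, SE 0.244, adjusted p = 8.42e-07), which hepatocytes of the periportal zone also express.

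Metabolic genes changed in both directions on chow. In the lipoprotein list 4 of 21 genes rose and 5 fell (4 and 5 when adjusted over the list alone), including the lipase Lpl (2.71, SE 0.216, adjusted p = 1.96e-07), the sorting receptor Sort1 (2.44, SE 0.274, adjusted p = 8.83e-06) and the receptor Vldlr (-1.62, SE 0.19, adjusted p = 1.09e-05). For triglyceride storage 5 of 19 rose and 1 fell (5 and 1 when adjusted over the list alone). The acyltransferase Mogat1 rose by 3.36 (SE 0.311, adjusted p = 8.18e-07) and the lipid droplet protein Cidec by 2.88 (SE 0.412, adjusted p = 0.000158), and Dgat2, the main hepatic triglyceride-forming enzyme, fell by 0.86 (SE 0.13, adjusted p = 0.000117). Glucose metabolism genes fell in 4 of 17 and rose in none (4 and none when adjusted over the list alone), with Fbp1, a gluconeogenic phosphatase, at -0.78 (SE 0.108, adjusted p = 5.31e-05). The glucose list had a median of -0.31 and a camera adjusted p of 0.00499, and adjusted p = 0.236 with an estimated correlation. Bile acid transporters and FXR targets fell in 7 of 17 and rose in 2 (8 and 2 when adjusted over the list alone), with the bile acid importer Slc10a1 at -0.93 (SE 0.107, adjusted p = 6.91e-06). In bile acid synthesis 3 of 16 rose and 4 fell (4 and 6 when adjusted over the list alone), with Cyp7b1 of the alternative pathway at 0.86 (SE 0.102, adjusted p = 1.01e-05). Cholesterol synthesis genes fell in 7 of 25 and rose in none (7 and none when adjusted over the list alone; median -0.32, camera adjusted p = 0.00849, adjusted p = 0.775 with an estimated correlation). Without WT chow replicate 3 or LKO chow replicate 2 the adjusted p of the cholesterol list was 0.0632 or 0.062. Fatty acid synthesis had 2 falls of 18 (2 when adjusted over the list alone), and fatty acid oxidation and PPARA targets 5 rises and 3 falls of 26 (5 and 3 when adjusted over the list alone).

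Of the lists of secreted proteins, zonation, stress and other functions below, camera called those of acute phase proteins, periportal genes and clock genes on chow, and none of the others. Acute phase proteins fell in 9 of 20 and rose in 1 (10 and 2 when adjusted over the list alone), with Lbp, which binds bacterial lipopolysaccharide, at -1.27 (SE 0.154, adjusted p = 1.38e-05). Camera gave the acute phase list adjusted p = 0.00393, and adjusted p = 0.333 with an estimated correlation. Periportal genes fell in 9 of 17 and rose in 1 (10 and 2 when adjusted over the list alone), with the urea cycle enzyme Otc at -0.72 (SE 0.11, adjusted p = 0.000139) and a camera adjusted p of 0.00499, and adjusted p = 0.307 with an estimated correlation. Circadian clock genes fell in 4 of 17 (5 when adjusted over the list alone; camera adjusted p = 0.00855, adjusted p = 0.103 with an estimated correlation), among them Hlf (-0.69, SE 0.111, adjusted p = 0.000227). The clock call was lost when LKO chow libraries 1 and 2 were left out. Hepatocyte transcription factors and secreted proteins rose in 2 and fell in 6 of 16 (2 and 8 when adjusted over the list alone). Pericentral genes rose in 5 and fell in 1 of 16, the same when adjusted over the list alone. Xenobiotic metabolism genes rose in 6 and fell in 5 of 25, NRF2 targets rose in 4 and fell in 2 of 14, and integrated stress response genes rose in 5 and fell in 1 of 15. These last 3 counts were the same when adjusted over the list alone. Unfolded protein response genes fell in 2 of 16 (1 when adjusted over the list alone). Gdf15, a secreted stress factor of the integrated stress response list, rose by 1.99 (SE 0.268, adjusted p = 6.91e-05), and Nr1i2, the xenobiotic receptor PXR, fell by 0.66 (SE 0.081, adjusted p = 1.49e-05). Glucocorticoid receptor targets rose in 1 and fell in 2 of 20 (1 and 1 when adjusted over the list alone). Immediate early genes rose in 4 of 15, and cell cycle genes in 1 of 21, which was Ccnd1, cyclin D1 (1.06, SE 0.264, adjusted p = 0.0085). Mitochondrially encoded genes fell in 2 of 13 and red blood cell genes rose in 1 of 7. These last 4 counts were the same when adjusted over the list alone. Of the short lists not tested as sets, adipocyte genes held 1 rise of 3 and pancreas genes none of 3.

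Camera called 11 of 35 lists on chow, 3 of them with an estimated correlation, and fry called 15. The chow gene count rests in part on the libraries used: it was 2373 without LKO chow libraries 3 and 4 and 2152 when the chow libraries were fitted alone. The camera list count was 17 without WT chow replicate 2. Which direction held more genes depended on the tool, the scaling and the libraries. There were 1895 higher and 2070 lower genes in DESeq2, 1914 and 1995 with limma voom, 1758 and 1860 with DESeq2 size factors, 2123 and 1401 with upper-quartile scaling, and 2413 and 2623 without LKO chow libraries 1 and 2.

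The same genotype comparison on HFD asked which of these differences were present under the high-fat diet. Most p53 targets, interferon-stimulated genes and male-biased genes again rose, and most splicing regulators and 8 of 20 female-biased genes fell. Of these 5 lists, those of p53 targets and male-biased genes were also called with an estimated correlation between genes. Fry called all 5, with a highest adjusted p of 0.00151 for the splicing regulators. Slc1a1, a glutamate transporter (chromosome 19, 28835049 to 28913960), rose by 5.48 (SE 0.303, adjusted p = 2.5e-09), Psrc1 by 5.50 (SE 0.235, adjusted p = 6.97e-11) and Aqp7 by 4.73 (SE 0.255, adjusted p = 2.5e-09). Cyp4a12a stood at 0.235 ± 0.0636 CPM in WT and 20.2 ± 7.99 CPM in LKO (SD, n = 4 each), a log2 fold change of 6.37 (SE 0.421, adjusted p = 3.67e-08). The sulfotransferase Sult2a3 fell by 3.83 (SE 0.504, adjusted p = 0.000124), though its reads may be shared with close copies. In all, 2583 of 14434 genes (17.9%) were called, 1491 higher and 1092 lower, with 573 and 124 of them changed at least 2-fold.

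On HFD 12 of 13 p53 targets rose and none fell (12 and none when adjusted over the list alone), with a median of 1.84, a camera adjusted p of 7.43e-16 and adjusted p = 0.0102 with an estimated correlation. Eda2r, a receptor of the tumour necrosis factor receptor family, rose by 4.09 (SE 0.323, adjusted p = 3.3e-07) and Phlda3 by 3.78 (SE 0.162, adjusted p = 6.97e-11). Interferon-stimulated genes rose in 16 of 20 and fell in none (18 and none when adjusted over the list alone; median 1.54, camera adjusted p = 1.3e-10, adjusted p = 0.35 with an estimated correlation), among them Oas1a (2.53, SE 0.179, adjusted p = 4.07e-08) and Ifit3 (2.10, SE 0.317, adjusted p = 0.000301). Male-biased genes rose in 10 of 15 and fell in none (11 and 1 when adjusted over the list alone), with a camera adjusted p of 2.73e-08 and adjusted p = 0.0102 with an estimated correlation. Female-biased genes fell in 8 of 20 and rose in none (13 and 1 when adjusted over the list alone; median -1.19, camera adjusted p = 2.2e-06, adjusted p = 0.107 with an estimated correlation). Serine/arginine-rich splicing regulators fell in 18 of 26 and rose in none (19 and none when adjusted over the list alone; median -0.41, camera adjusted p = 3.62e-09, adjusted p = 0.35 with an estimated correlation). Their mean log2 CPM was 5.67 ± 0.04 in LKO and 6.07 ± 0.11 in WT (SD, n = 4 each). The kinases Clk1 and Clk4, which phosphorylate such proteins, fell by 0.88 (SE 0.155, adjusted p = 0.000646) and 0.96 (SE 0.17, adjusted p = 0.00069), and Srsf5 fell by 0.70 (SE 0.107, adjusted p = 0.000169).

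**Figure D2:**
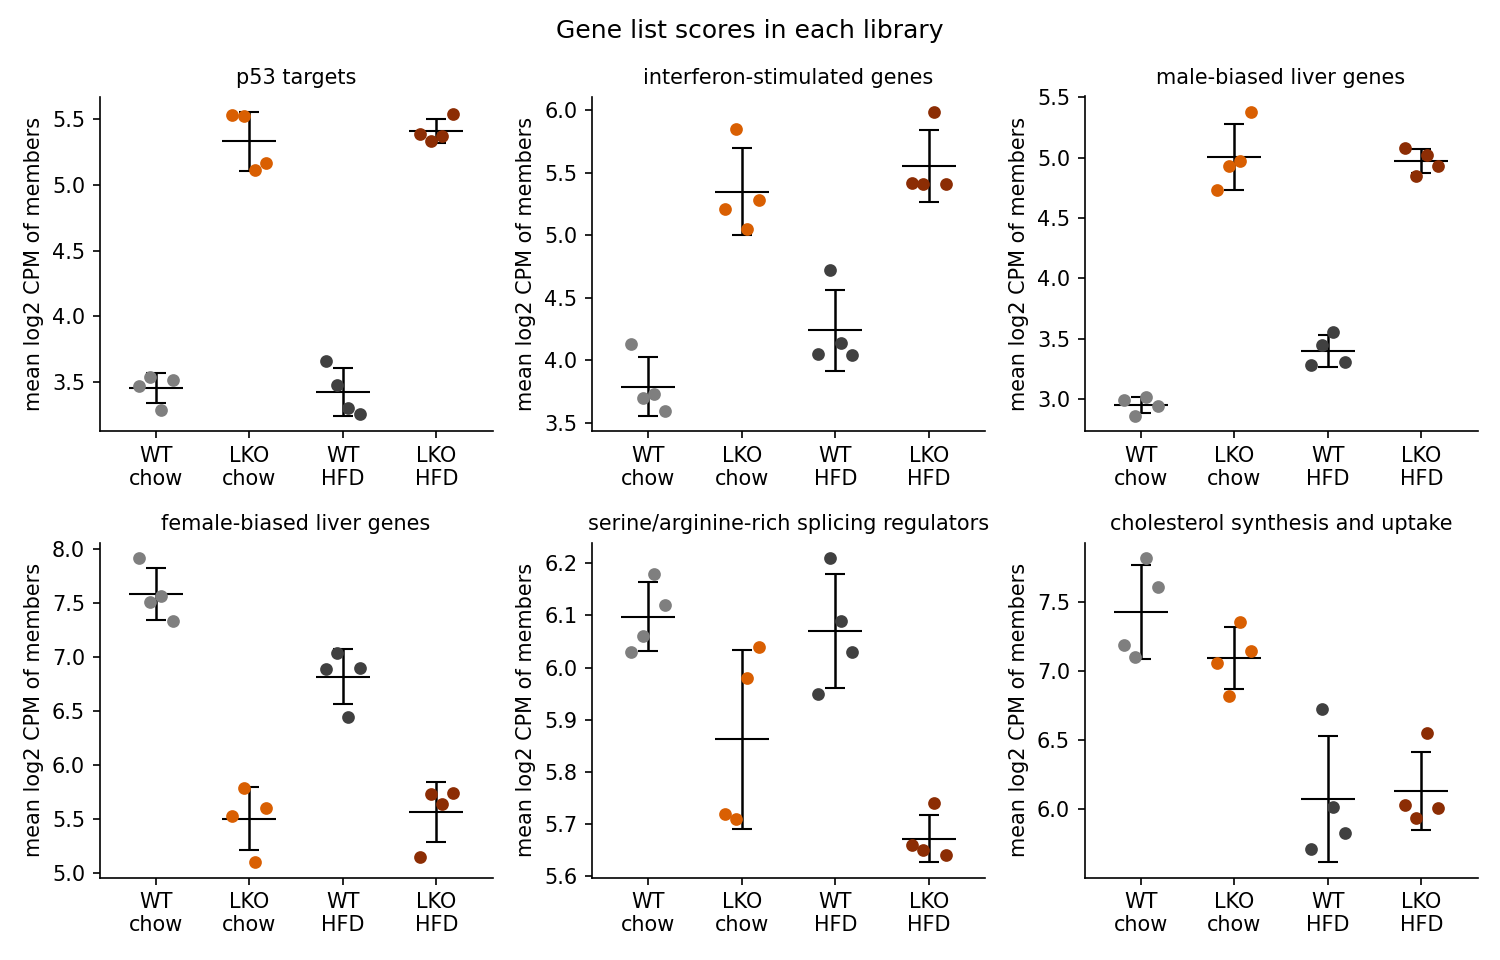
Mean log2 CPM of the members of 6 gene lists (vertical axes, which do not start at 0) in each library, by group, with the group mean and SD. The p53 list averages 5.33 and 5.41 in LKO on chow and HFD against 3.45 and 3.43 in WT.

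Lipid and bile acid genes on HFD followed in part the pattern on chow. Cidec was higher by 2.80 (SE 0.376, adjusted p = 0.000121), Mogat1 by 2.5 (SE 0.275, adjusted p = 7.25e-06) and Lpl by 1.5 (SE 0.205, adjusted p = 7.46e-05), and Dgat2 fell by 0.51 (SE 0.129, adjusted p = 0.0105). Cyp8b1, the sterol 12-alpha-hydroxylase that sets the cholic acid share (chromosome 9, 121914356 to 121916305), fell by 1.56 (SE 0.322, adjusted p = 0.00335), and the bile acid importer Slc10a1 fell by 0.70 (SE 0.106, adjusted p = 0.000173). G6pc, the last enzyme of glucose release, fell by 1.25 (SE 0.308, adjusted p = 0.0102). Bile acid transport genes and FXR targets fell in 5 of 17 and rose in 1 (8 and 3 when adjusted over the list alone), and bile acid synthesis genes rose in 2 and fell in 1 of 16. Lipoprotein genes rose in 4 and fell in 1 of 21 (4 and 2 when adjusted over the list alone). Triglyceride storage genes rose in 2 and fell in 1 of 19, fatty acid oxidation genes rose in 3 and fell in 1 of 26, and glucose metabolism genes fell in 3 of 17. Fatty acid synthesis genes fell in 2 of 18 (none when adjusted over the list alone), and none of 25 cholesterol synthesis genes was called either way. Where no second count is given, it was the same when adjusted over the list alone. None of these 8 lists was called by camera.

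Mitochondrially encoded genes fell in 5 of 13 and rose in none on HFD (7 and none when adjusted over the list alone), with mt-Nd2 at -0.62 (SE 0.14, adjusted p = 0.00454). Camera called the list (median -0.44, adjusted p = 0.00102, adjusted p = 0.804 with an estimated correlation). These genes took 5.71 ± 0.469% of counts in LKO and 7.24 ± 0.646% in WT on HFD (SD, n = 4 each; exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.143 after adjustment over 20 library tests). Cyp2b10, an inducible cytochrome of xenobiotic metabolism, rose by 3.47 (SE 0.317, adjusted p = 2.45e-06), Gdf15 by 2.21 (SE 0.266, adjusted p = 2.96e-05) and Btg2, an antiproliferative early response gene, by 2.26 (SE 0.29, adjusted p = 6.36e-05). Lgr5, a pericentral Wnt pathway receptor, fell by 1.09 (SE 0.176, adjusted p = 0.000298). Markers of Kupffer cells, macrophages and monocytes, B and plasma cells, neutrophils, endothelial cells and matrix-forming cells held no called gene on HFD. T and NK cell genes rose in 1 of 16 (none when adjusted over the list alone) and bile duct cell genes in 2 of 12 (2 rose and 3 fell when adjusted over the list alone). Integrated stress response genes rose in 4 of 15 and unfolded protein response genes in 5 of 16, among them the chaperone Calr (0.51, SE 0.13, adjusted p = 0.0104). Acute phase proteins rose in 2 and fell in 2 of 20 (2 and 4 when adjusted over the list alone), and NRF2 targets rose in 3 and fell in 1 of 14 (4 and 1 when adjusted over the list alone). Xenobiotic metabolism genes rose in 5 and fell in 6 of 25, and pericentral genes rose in 2 and fell in 3 of 16. Periportal genes rose in 3 and fell in 3 of 17 (3 and 5 when adjusted over the list alone), and hepatocyte factors rose in 1 and fell in 2 of 16. Glucocorticoid receptor targets rose in 1 and fell in 1 of 20, and clock genes fell in 1 of 17. Immediate early genes rose in 4 of 15, cell cycle genes in 1 of 21 and red blood cell genes in 1 of 7. Where no second count is given, it was the same when adjusted over the list alone. Adipocyte and pancreas genes held none of 3 each (1 rise each when adjusted over the list alone).

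Camera called 6 of 35 lists on HFD, 2 of them with an estimated correlation, and 10 without WT HFD replicate 4. Fry called 9. The gene count on HFD was 4511 with limma voom and quality weights.

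The genotype differences on the 2 diets, which share no library, overlapped. Of the genes called, 1060 were higher in LKO on both diets, where 192.9 were expected for independent calls (odds ratio 37), and 709 were lower on both (128.5 expected, odds ratio 23.1). Only 3 genes were called in opposite directions. Among the 4376 genes called on either diet, 4096 (93.6%) had the same sign on both. Across all 14434 genes the log2 fold changes correlated with Pearson r = 0.773 and Spearman rho = 0.614, where genes are not independent replicates. Because 1 fit gave both comparisons a shared estimate of the spread of each gene, the odds ratios may overstate the overlap.

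**Figure D3:**
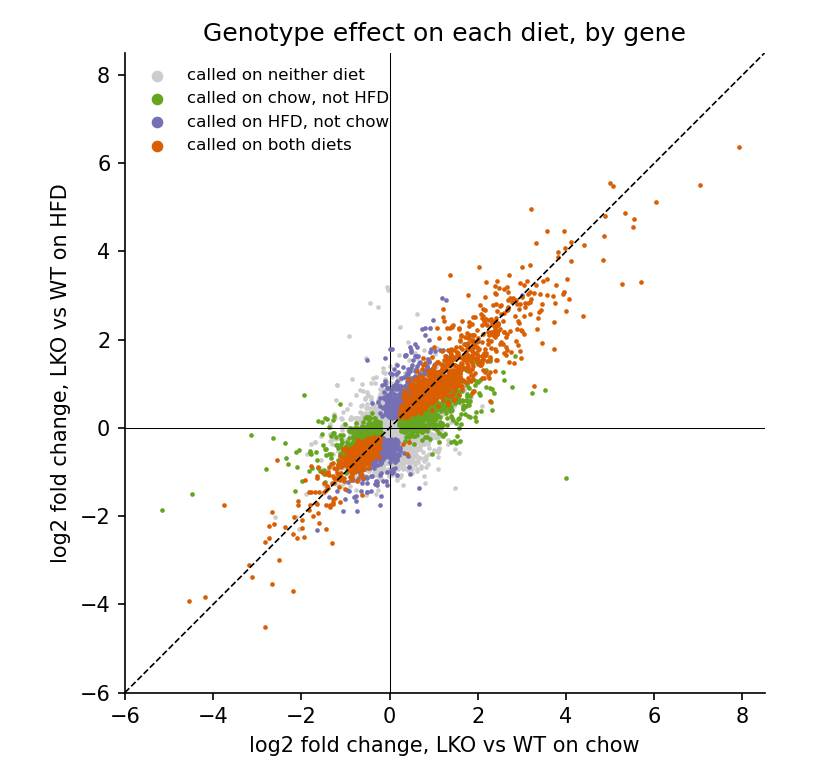
Log2 fold change of LKO against WT on chow (horizontal axis) and on HFD (vertical axis), one point per gene. Of the genes called on either diet, 93.6% have the same sign on both.

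The third comparison asked what the high-fat diet did in WT liver. Genes of cholesterol synthesis fell on HFD, and the sterol exporters Abcg5 and Abcg8 rose. Squalene epoxidase, Sqle (chromosome 15, 59315077 to 59331192), fell by 3.23 on the log2 scale (SE 0.454, adjusted p = 0.00195) and the isomerase Idi1 (chromosome 13, 8885501 to 8892451) by 2.46 (SE 0.234, adjusted p = 2.74e-05). Abcg5 (chromosome 17, 84658234 to 84683011) rose by 2.09 (SE 0.176, adjusted p = 5.38e-06) and Abcg8 (chromosome 17, 84676302 to 84700333) by 1.87 (SE 0.156, adjusted p = 5.38e-06). These neighbours overlap on opposite strands, so reads in the overlap may be counted to either. In all, 294 of 14434 genes were called, 140 higher and 154 lower on HFD.

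Cholesterol synthesis and uptake genes fell in 15 of 25 and rose in none in WT (23 and none when adjusted over the list alone), with Msmo1 at -2.08 (SE 0.222, adjusted p = 7.92e-05). The mean log2 CPM of the list was 6.07 ± 0.46 on HFD and 7.43 ± 0.35 on chow (SD, n = 4 each). Camera gave a median of -1.24 and adjusted p = 7.81e-33, and adjusted p = 0.0601 with an estimated correlation. Among the largest rises were Gpnmb, a glycoprotein of lipid-laden macrophages (2.41, SE 0.331, adjusted p = 0.000609), the macrophage elastase Mmp12 (2.52, SE 0.393, adjusted p = 0.00221), the sphingomyelinase Smpd3 (2.40, SE 0.259, adjusted p = 6.88e-05) and the urinary protein Mup17 (3.6, SE 0.349, adjusted p = 6.88e-05). Macrophage and monocyte genes rose in 3 of 20 (6 when adjusted over the list alone; median 0.57, camera adjusted p = 1.64e-08, adjusted p = 0.182 with an estimated correlation). Extracellular matrix and stellate cell genes rose in 3 of 23 (14 when adjusted over the list alone; median 0.53, camera adjusted p = 1.57e-09, adjusted p = 0.201 with an estimated correlation), with the collagens Col3a1 (1.03, SE 0.176, adjusted p = 0.00429) and Col1a2 (1.02, SE 0.195, adjusted p = 0.0101).

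**Figure D4:**
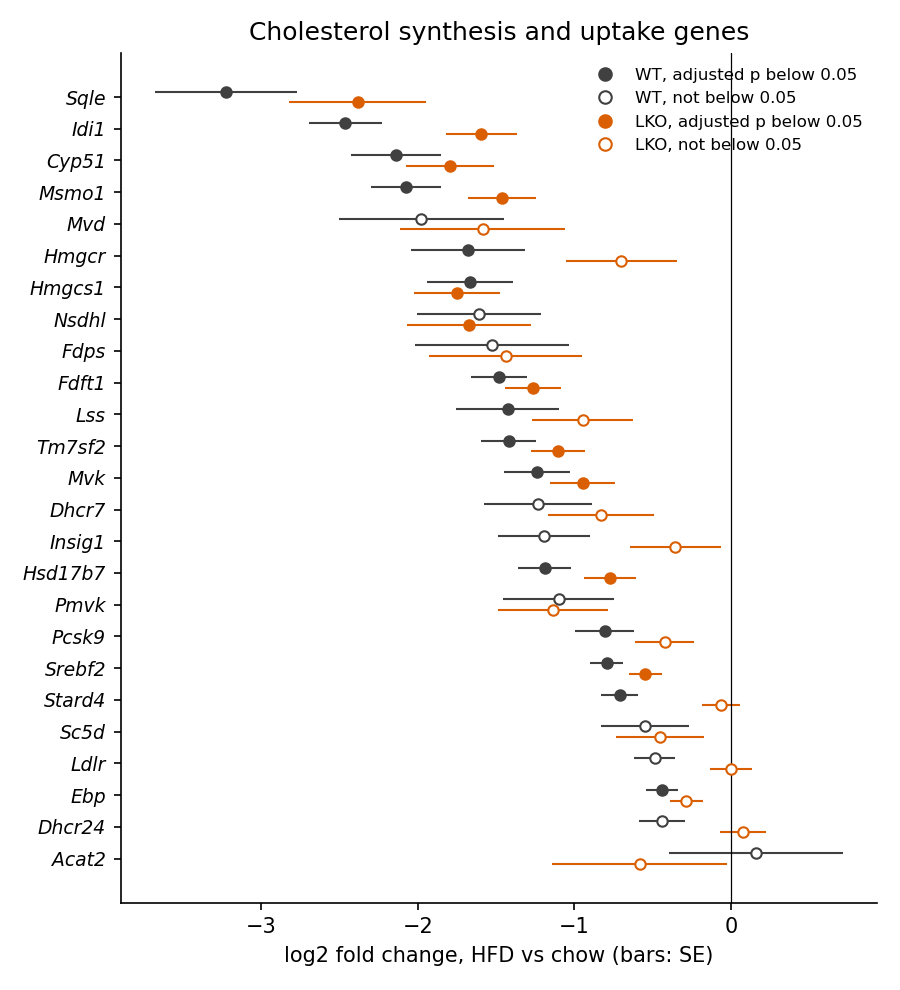
Log2 fold change of HFD against chow (horizontal axis, bars give the SE) of the 25 cholesterol synthesis and uptake genes, in WT (dark) and LKO (orange), with filled points for adjusted p below 0.05. In WT 15 genes fell and in LKO 11, and none rose in either.

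Of the other lists called in WT, triglyceride storage genes rose in 4 of 19 (8 when adjusted over the list alone; camera adjusted p = 0.00682, adjusted p = 0.315 with an estimated correlation, and 0.0541 without WT chow replicate 3). Female-biased genes fell in 2 of 20 (10 when adjusted over the list alone; camera adjusted p = 5.46e-06, adjusted p = 0.135 with an estimated correlation). Male-biased genes rose in 4 of 15 (5 when adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.201 with an estimated correlation), among them Elovl3, a fatty acid elongase (1.78, SE 0.3, adjusted p = 0.00381). Periportal genes fell in 4 of 17 (6 when adjusted over the list alone; camera adjusted p = 4.94e-08, adjusted p = 0.0601 with an estimated correlation). Hepatocyte transcription factors and secreted proteins fell in 2 of 16 (5 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.00141, adjusted p = 0.21 with an estimated correlation), with albumin, Alb, at -0.74 (SE 0.113, adjusted p = 0.00179). Interferon-stimulated genes rose in 2 of 20 (5 when adjusted over the list alone; camera adjusted p = 1.58e-05, adjusted p = 0.442 with an estimated correlation). Cell cycle genes rose in 1 of 21 (3 when adjusted over the list alone; median 1.01, camera adjusted p = 4.73e-07, adjusted p = 0.412 with an estimated correlation). Unfolded protein response genes held no called gene of 16, at a median of -0.28 (camera adjusted p = 5.63e-06, adjusted p = 0.315 with an estimated correlation). B and plasma cell genes held none of 13, at -0.36 (camera adjusted p = 0.0293, adjusted p = 0.726 with an estimated correlation). The call for B and plasma cells, HFD vs chow in WT, was lost without WT chow replicate 2 (0.374), WT chow replicate 3 (0.0695) or WT HFD replicate 4 (0.253). Lpl rose by 1.24 (SE 0.208, adjusted p = 0.00427), and Cyp3a11, a drug-metabolising cytochrome, by 1.25 (SE 0.13, adjusted p = 4.24e-05), in lists not called as a whole. In bile acid synthesis 1 of 16 rose and 2 fell (4 and 2 when adjusted over the list alone). In bile acid transport 2 of 17 rose and 1 fell (2 and 3 when adjusted over the list alone), the fall being the bile salt exporter Abcb11 (-0.54, SE 0.103, adjusted p = 0.00902). Acute phase proteins rose in 1 of 20 and fell in 4 in WT (4 and 6 when adjusted over the list alone), at a camera adjusted p of 0.21.

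Camera called 12 of 35 lists in WT and none with an estimated correlation. Fry called 8, among them cholesterol synthesis (adjusted p = 0.0011). The WT diet count was 155 without WT HFD replicate 3, 182 without WT chow replicate 4, 193 without WT HFD replicate 4, and 706 with DESeq2, 470 with limma voom and 776 with a clock score in the fit.

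The fourth comparison asked the same of LKO liver. Cholesterol synthesis genes fell on HFD here too, in 11 of 25 with none rising (17 and none when adjusted over the list alone). Idi1 fell by 1.60 (SE 0.227, adjusted p = 0.00226), Msmo1 by 1.46 (SE 0.218, adjusted p = 0.00275) and squalene synthase, Fdft1, by 1.27 (SE 0.179, adjusted p = 0.0018). Abcg5 rose by 1.32 (SE 0.172, adjusted p = 0.00114) and Abcg8 by 1.09 (SE 0.152, adjusted p = 0.0018). The list averaged 6.13 ± 0.28 on HFD and 7.10 ± 0.22 on chow (log2 CPM, SD, n = 4 each). It was called with a median of -0.95 and a camera adjusted p of 1.85e-16, and adjusted p = 0.618 with an estimated correlation.

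Other rises in LKO on HFD were those of the acute phase protein Orm2 (1.87, SE 0.32, adjusted p = 0.00735), the T cell protein Themis (1.96, SE 0.31, adjusted p = 0.00275) and Mup17 (2.03, SE 0.318, adjusted p = 0.00446). The chloride channel protein Clic3 fell by 2.43 (SE 0.36, adjusted p = 0.00239) and the prostaglandin synthase Ptgds by 2.41 (SE 0.377, adjusted p = 0.00275). Macrophage and monocyte genes rose in 3 of 20 (4 when adjusted over the list alone; median 0.44, camera adjusted p = 6.94e-05, adjusted p = 0.618 with an estimated correlation). Acute phase proteins rose in 1 of 20 (6 when adjusted over the list alone; camera adjusted p = 0.00446, adjusted p = 0.618 with an estimated correlation). Splicing regulators held no called gene of 26 (3 falls when adjusted over the list alone; median -0.20, camera adjusted p = 2.49e-05, adjusted p = 0.847 with an estimated correlation). Clock genes rose in 2 and fell in 3 of 17 (8 and 4 when adjusted over the list alone; camera adjusted p = 0.169). Nr1d2, a clock repressor, rose by 1.09 (SE 0.203, adjusted p = 0.00988), though its adjusted p reached 0.125 with a clock score in the fit or with the LKO libraries fitted alone. A score of clock phase, Dbp, Tef, Per2 and Per3 less Arntl, Npas2 and Clock in mean log2 CPM, averaged 1.34 ± 1.41 in WT on chow, 0.02 ± 1.95 in LKO on chow, 3.18 ± 0.78 in WT on HFD and 3.45 ± 0.86 in LKO on HFD (SD, n = 4 each). These genes were chosen after their values were seen.

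In LKO 320 of 14434 genes were called, 165 higher and 155 lower on HFD, and camera called 4 of 35 lists and none with an estimated correlation. Fry called only the cholesterol list (adjusted p = 0.0442). The camera list count was 8 without LKO chow replicate 2, 7 without LKO HFD replicate 2, 9 without LKO chow libraries 1 and 2 and 11 with a clock score in the fit. The LKO diet count was 111 without LKO HFD replicate 1, 118 without LKO HFD replicate 2, 127 without LKO HFD replicate 4 and 117 without LKO chow replicate 3. It was 196 without LKO chow replicate 4, 656 without LKO chow replicate 2 and 2768 without both LKO chow libraries 1 and 2. It was 179 without LKO chow libraries 3 and 4, 188 with the LKO libraries fitted alone, 779 with DESeq2, 2021 with limma voom and 2410 with a clock score in the fit.

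The diet responses of the genotypes, which share no library, overlapped in 40 higher genes (1.6 expected, odds ratio 45.3, one-sided Fisher exact p across genes 9.65e-46) and 44 lower genes (1.7 expected, odds ratio 50.9, p = 8.93e-52), with none in opposite directions. These 84 shared genes numbered 43 without LKO HFD replicate 1, 45 without LKO HFD replicate 2 or 4 and 50 without LKO chow replicate 3. They numbered 52 with only the groups compared, 170 without LKO chow libraries 1 and 2, 194 with DESeq2, 168 with limma voom and 436 with a clock score in the fit. Log2 fold changes correlated across genes with Pearson r = 0.414 and Spearman rho = 0.291, where genes are not independent replicates. Both responses also come from 1 fit with a shared estimate of the spread of each gene. The Fisher p-values and odds ratios may therefore overstate the overlap.

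Whether the genotypes differed in their response to diet was tested by the interaction. Lepr, the leptin receptor (chromosome 4, 101717404 to 101815352), went from 5.83 ± 1.54 to 25 ± 4.29 CPM in WT and from 15.9 ± 4.42 to 20.2 ± 2.61 CPM in LKO (SD, n = 4 each; interaction -1.76, SE 0.278, adjusted p = 0.0413). Adam11, a catalytically inactive member of the ADAM family (chromosome 11, 102761439 to 102780262), went from 17.5 ± 3.6 to 120 ± 20.4 CPM in WT and from 85.0 ± 24.6 to 183 ± 6.44 CPM in LKO (interaction -1.66, SE 0.264, adjusted p = 0.0413, edgeR). Ppp4r4, a phosphatase subunit (chromosome 12, 103532283 to 103613831), went from 22.1 ± 1.21 to 13.4 ± 0.775 CPM in WT and from 23.4 ± 2.65 to 24.9 ± 1.53 CPM in LKO (interaction 0.81, SE 0.128, adjusted p = 0.0413). These 3 were the genes called of 14434, 1 higher and 2 lower, against 48 (29 higher and 19 lower) with DESeq2 and 16 with limma voom, and 1263 had an unadjusted p under 0.05 where 722 are expected by chance. Camera called 11 lists, none of which was called with an estimated correlation. By edgeR 1264 genes were called without LKO chow libraries 1 and 2 and 22 with a clock score in the fit. No gene was called by edgeR with a replicate block (1141 at an unadjusted p under 0.05) or among genes with a mean count of at least 50 (1096). Each of the 3 gene calls was lost in most fits that left out 1 library, where the count of genes ran from 0 to 9 (9 without LKO chow replicate 1 and 5 without LKO HFD replicate 3).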

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

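The tests of Y-linked counts, of gene families, of immune cell markers and of collection time were chosen only after the result each bears on was seen, as were the genes of the clock score and the use of this score as a term in the fit; the bounds for the cholesterol genes with that term, the regrouped libraries and the interferon gap and scaling were written after the patterns but before these values were seen.

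The first pattern is the fall of female-biased and rise of male-biased liver genes in LKO. Male animals among the LKO mice could give it, and the Y-linked genes do not decide: Ddx3y, Eif2s3y and Uty together reached at most 25.4 counts in an LKO library against 30.5 in WT, but Kdm5d, left out of this sum after its counts were seen, stood at 58.7 to 93.4 in LKO and 23.9 to 49.5 in WT on chow (log2 fold change 0.99, adjusted p = 0.0157) and at 60.4 to 92 and 21.3 to 49.8 on HFD, and with it the sum reached 118.8 in LKO and 80.3 in WT. Reads shared between near-identical copies are unlikely for the male-biased rise, since members outside such families had a median of at least 1.22 on both diets, and for the female-biased fall on chow, where 6 of 8 members outside the families fell at a median of -1.35. On HFD the members outside had a median of only -0.30 with 1 of 8 falling, against -1.80 inside. Shared reads are thus not excluded for the female-biased fall there, and their part was not measured. The list mean in WT was also lower on HFD (6.82 log2 CPM) than on chow (7.58), while in LKO it was 5.56 and 5.5. A hormonal or growth-signal cause in LKO mice was not tested.

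The second pattern is the fall of cholesterol synthesis genes on HFD while clock genes also differed between diets. With the clock score in the fit the WT median was -1.48 (-1.24 without it) and 18 genes fell in place of 15, so a linear effect of the score did not account for the fall. The score overlapped little between diets, however. Its highest chow and lowest HFD values were 3.11 and 2.46 in WT, and 1.99 and 2.31 in LKO. In WT only chow library 4 (3.11) lay within the HFD range, and in LKO the fit extrapolates between diets. The cholesterol list scores did not overlap between diets in either genotype. With so little shared range of the clock score, the fit cannot exclude clock phase as the cause. The clock score was higher on HFD by 1.84 in WT (exact permutation p = 0.0857) and by 3.43 in LKO (exact permutation p = 0.0286, 0.0572 after adjustment over both), in part because LKO chow libraries 1 and 2 stood at -0.95 and -2.22 and libraries 3 and 4 at 1.27 and 1.99. Tissue collected at another hour could give this difference, and it cannot be told apart from an effect of diet on the clock, because collection times are not given. The effect of the diet itself on the cholesterol genes remains an open biological explanation.

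The third pattern is the rise of interferon-stimulated genes in LKO. More immune cells in the tissue are unlikely, since 59 pooled immune cell markers had medians of -0.07 on chow and -0.024 on HFD, against 1.92 and 1.54 for the interferon list. A few affected animals could not give it alone, as the lowest LKO library stood above the highest WT library by 0.93 on chow and 0.69 on HFD (log2), more than the larger SD of 0.35 and 0.33. Scaling between libraries did not remove it either, with a smallest median rise of 1.52 under upper quartile and DESeq2 size factors. A response within hepatocytes that lack Arglu1 is a hypothesis these data leave open. The list was not called with an estimated correlation between genes (adjusted p = 0.236 and 0.35), though fry called it on chow and HFD (adjusted p = 7.54e-05 and 0.000399).

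Other splits of the libraries were counted for each comparison. The real split gave more genes than any other in each comparison of 2 groups. For genotype on chow 1 of 35 splits reached 3565 (highest other 1249), and on HFD 1 of 35 reached 2583 (highest other 1). For diet in WT 1 of 35 reached 294 (highest other 4), and in LKO 1 of 35 reached 320 (highest other 0). This makes chance unlikely but cannot exclude it, because 1 of 35 is the smallest share possible. The other splits also mix the real groups, which widens the spread within groups and tends to lower their counts. The split with 1249 genes joined WT chow libraries 2 and 3 with LKO chow libraries 1 and 2, which points to a structure among the chow libraries besides genotype. For the interaction 4 of 100 splits gave at least 3 genes, with up to 57 in another, which points to a structure of the libraries besides their groups. These splits shuffle the diet within each genotype, which also breaks up the diet effect and widens the spread within groups. The share is thus no test of the interaction alone. It cannot exclude chance for these 3 genes, which were also not called with a replicate block. The number of lists called was not unusual among these splits in any comparison: 16 of 35 splits gave at least the 11 lists on chow (highest other 21), 32 of 35 the 6 on HFD (13), 12 of 35 the 12 for diet in WT (16), 33 of 35 the 4 for diet in LKO (14) and 39 of 100 the 11 of the interaction (16). A split that swaps few libraries keeps part of the real contrast, and a count ignores how strongly each list was called. These shares therefore do not bear on any single list. In list scores compared after these splits were seen, 9, 10, 8 and 4 of 35 lists did not overlap between the groups of the 4 comparisons, where 1 is expected by chance for each. No list passed after Benjamini-Hochberg adjustment of its exact permutation p (lowest adjusted p 0.111, 0.1, 0.125 and 0.25). With 0.0286 the smallest p possible, a list could pass over 35 lists only if most lists did not overlap. The adjusted values therefore do not speak against any single list. The list scores come from the same libraries and are not independent, so the excess over 1 may be overstated.

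In 13 of 300 groups of 4 libraries, where 15 are expected by chance, 1 library stood far from the other 3, measured by its gap to the nearest as a share of the range. This share was 0.847 for Arglu1 in WT on chow (library 2, 45.1 CPM). In LKO on HFD, library 3 stood apart for the scores of cholesterol synthesis (0.853), fatty acid synthesis (0.93), interferon-stimulated genes (0.979) and splicing regulators (0.859) and for Sqle (0.925), and library 2 for Ldb3 (0.879). In WT on HFD, library 2 stood apart for glucose metabolism (0.842), neutrophils (0.838) and interferon-stimulated genes (0.846). On chow, it was LKO library 1 for pericentral genes (0.831), LKO library 4 for Cyp4a12a (0.884) and WT library 4 for Nat8f7 (0.947).

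By edgeR the effect of genotype differed between diets for Adam11 (interaction log2 fold change -1.66), Lepr (-1.76) and Ppp4r4 (0.81), but no gene was called with a replicate block (1141 at an unadjusted p under 0.05) or among genes with a mean count of at least 50 (1096). Other fits called more, 48 with DESeq2, 16 with limma voom, 22 with the clock score in the fit and 1264 without LKO chow libraries 1 and 2. By camera the genotype effect also differed for 11 lists, with interaction medians of 0.38 for cholesterol synthesis, 0.49 for female-biased genes, -0.36 for male-biased genes, -0.41 for extracellular matrix, -0.53 for endothelial cells (0.251 without LKO chow libraries 1 and 2), -0.75 for cell cycle, 0.46 for the unfolded protein response, 0.41 for acute phase proteins, 0.34 for periportal genes, -0.20 for splicing regulators and 0.44 for clock genes. None of these lists was called with an estimated correlation or by fry.

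Genes absent from the counts table were tested from the second table, 328 in all. Of these 123 were called for genotype on chow (105 higher, 18 lower) and 117 on HFD (106 higher, 11 lower), 2 for diet in WT, 5 for diet in LKO and 0 for the interaction.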

How the results depend on the processing

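Across the alternatives, of 7017 tests of named genes 6372 kept direction and call, 645 lost the call and none turned, and of 836 tests of called lists 743 kept it, 92 lost it and 1 turned. Arglu1 kept its fall in every alternative. The 3 limma-trend fits on RPKM that were set in advance were not run, because no table holds RPKM. Except where fewer libraries or a stricter threshold explain the value, the cause was not tested. The second table, the left-out pairs of LKO chow libraries, the clock term and the Acat2 value were chosen after seeing the data.

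For genotype on chow (3565 genes), 2152 were called with the chow libraries alone, 2373 without LKO chow libraries 3 and 4 (1942 of them shared) and 905 with a fold minimum of 2. Lists on chow numbered 11, 3 with an estimated correlation, 15 with fry, 19 without LKO chow libraries 3 and 4, and 11 to 17 when 1 library was left out. For genotype on HFD (2583 genes), limma voom gave 4511 and the fold minimum 697. Lists there numbered 6, 2 with an estimated correlation, 9 with fry and 6 to 10 when 1 library was left out.

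For diet in WT (294 genes), DESeq2 gave 706, limma voom 470, the second table as deposited 16629, the fits without LKO chow libraries 1 and 2 or 3 and 4 618 and 502, the clock term 776, the fold minimum 108 and leaving out 1 library 155 to 322. Of 12 lists 0 were called with an estimated correlation, and fry called 8. For diet in LKO (320 genes), DESeq2 gave 779, limma voom 2021, the LKO libraries alone 188, the second table as deposited 16515, the fits without LKO chow libraries 1 and 2 or 3 and 4 2768 and 179, the clock term 2410, the fold minimum 90 and leaving out 1 library 111 to 656. Lists numbered 4, 9 without LKO chow libraries 1 and 2, 11 with the clock term, 0 with an estimated correlation, 1 with fry and 4 to 8 when 1 library was left out. The counts from the second table as deposited come from chow values set against the wrong gene.

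For the interaction (3 genes by edgeR, 1263 at an unadjusted p under 0.05), DESeq2 gave 48, limma voom 16, a mean count of at least 50 gave 0, a replicate block 0, the second table as deposited 2378, the fit without LKO chow libraries 1 and 2 1264, the clock term 22 and leaving out 1 library 0 to 9. Of 11 lists 0 were called with an estimated correlation and 0 with fry, and the endothelial median turned from -0.53 to 0.251 without LKO chow libraries 1 and 2. The genotype overlap of 1769 genes was 516 with the fold minimum. The diet overlap of 84 genes was 194 with DESeq2, 168 with limma voom, 52 with only the groups compared, 170 without LKO chow libraries 1 and 2, 436 with the clock term, 33 with the fold minimum and 43 to 101 when 1 library was left out.

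In counts simulated at the depth and spread of these libraries, with few genes changed and genes drawn independently, 40.3% to 47.8% of 1.5-fold changes were recovered in comparisons of 2 groups and 17.9% in the interaction. Depth was not varied, so its part in this limit was not told apart from that of the spread between libraries. Upper-quartile scaling took the median log2 fold change of all genes in the interaction from -0.017 to -0.081 and moved it less in the other comparisons (on chow from 0.023 to 0.069). It turned the balance of calls for diet, to 160 higher and 140 lower in WT and 141 higher and 186 lower in LKO.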

Other observations

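The tests of cilia genes and the choice of the genes below were made only after their values were seen; the test around Arglu1 was set before.

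Several genes silent or nearly so in WT liver were expressed in every LKO library, and the counts table omits them because some WT library held 0. The axonemal dynein Dnah5 stood at 0.021 CPM in WT and 12.3 CPM in LKO on chow (log2 fold change 8.69, adjusted p = 6.22e-10) and at 0.0691 and 11.7 CPM on HFD. The actin-binding protein Avil stood at 0.154 and 38.0 CPM on chow and at 0.0546 and 26.1 CPM on HFD, and the muscle kinase Alpk3 at 0.0812 and 3.82 CPM on chow. Cyp4a12b, Dnah9 and Cfap44 were at 0 in all 4 WT chow libraries and averaged 2.71, 0.876 and 0.877 CPM in LKO on chow. The reads of Cyp4a12b may be shared with its close copy Cyp4a12a, which also rose. The nicotinic receptor subunit Chrna9 was at 0 in all 4 WT HFD libraries and averaged 1.83 CPM in LKO on HFD.

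That cilia and flagella genes rise as a group is a hypothesis taken from those values. Of 41 such genes tested (Dnah, Dnai, Cfap, Rsph and Spag families), 13 were called higher in LKO on each diet, 31.7% against 13.2% of other genes on chow (one-sided Fisher exact p across genes = 0.00178) and 10.7% on HFD (p = 0.000244). Rsph4a of this group fell, by 3.18 on chow. Of those that rose on both diets, Cfap157, Cfap44, Dnah1, Dnah5 and Dnah9 come from outside the counts table. Among the 328 genes tested from there, 105 rose on chow and 106 on HFD, and the test did not match genes by level. The families were picked by gene name. Genes are not independent, and the family was chosen because some members stood out, so the p-values may overstate the grouping.

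Psrc1 and Sort1 are neighbours on chromosome 3 (108383839 to 108388231 and 108284082 to 108361511, mm10), and both rose in LKO, by 7.04 and 2.44 on chow and by 5.50 and 2.14 on HFD. Celsr2, which lies beside them, had log2 fold changes of -1.10 (adjusted p = 0.168) and -1.33 (adjusted p = 0.121) and was not called.

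Variants linked to the targeted locus could raise the share of called genes near Arglu1. Within 10 Mb of it on chromosome 8, 19 of 72 genes (26.4%) were called on chow, against 24.9% of 13852 elsewhere (one-sided Fisher exact p = 0.431), so no excess was detected, which leaves single linked genes open.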
